A study of Arabidopsis thaliana with 12 samples.

How the data were processed

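The 9 chromatin immunoprecipitation libraries, each against a different histone H3 modification, were analysed with 2 control libraries and 1 RNA library from Arabidopsis thaliana of the Col-0 ecotype. The chromatin came from aerial tissue of plants 2 weeks old grown on solid medium, and the RNA from young leaves of plants 21 to 28 days old grown in soil, per the labels. The controls were an immunoprecipitation against unmodified H3 and sonicated input chromatin, called Input. Each group held 1 library, so there was no replicate check, and every comparison is between libraries and not between conditions.

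The deposited files list aligned reads, 1 line per read, with chromosome, start, end and strand. The score column, as deposited by the authors, held the single value 900 in every library and was not used. No library held more than 1 read with the same start and strand on a chromosome, so repeated reads had been removed or collapsed before deposit, and the reads are positions rather than a full tally of molecules. The aligner and the genome build are not given in the sources used here, and how reads with several matching places were treated is not given either. The RNA library was made with a SOLiD kit after depletion of ribosomal RNA, per the labels. Every number below was computed from the deposited read positions with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9.

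Because no build was named, the use of gene names had to be settled from the reads. The reference table at hand lists genes of the TAIR10.1 assembly, without strands or exons. In 500 kb blocks, the share of RNA reads inside protein-coding genes of the table was computed with no shift. From the start of each chromosome up to 12500000 bp on chromosome 1, 2500000 on chromosome 2, 9000000 on chromosome 3, 11000000 on chromosome 5 and over all of chromosome 4, 99.0% of RNA reads fell inside those genes, against 63.8% elsewhere. Outside the stretches the coordinates differ over much but not all of the genome, since some blocks next to the stretches fell short only of the limits below. Genes were named and measured only in these stretches, which hold 53.6 of 119.2 Mb (45.0%), and no coordinate was converted. Genes elsewhere were not analysed here. The limits of the stretches, at least 90% of at least 2000 RNA reads in a block, were set after the block values had been seen. The build itself remains unnamed, and a gene inside the stretches whose model differs between builds would be measured over the wrong interval. Coordinates of regions are printed as the files give them, counted from 1, and none of the table's coordinates is printed.

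Reads were placed by their 5' end moved 60 bp downstream, RNA reads without the move, and counted in 100 bp steps. A gene took the steps whose centres it covers. Enrichment is the ratio of a mark's share of nuclear reads to that of H3, with the exact 95% (Clopper-Pearson, conditional binomial) interval. A gene or 1 kb window was called enriched where the ratio was at least 2, the lower limit above 1, and the 2 libraries together held at least 20 reads. Intervals cover counting error only. Libraries held 939015 (H3K9me2) to 3717703 reads (H3K36me3) among the marks, 5801693 in H3, 7279050 in Input and 4186884 in RNA.

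Several steps differ from the design fixed before the data were examined, since the table gives neither strand nor exons. RNA level is the number of reads on the gene's major strand over the whole gene, scaled to gene length and library size (RPKM). One read per position and strand means that abundant transcripts saturate: among the 200 genes of highest RPKM, the median share of start positions occupied was 38.8%, and the highest was 79.2%. Strand was assigned from the RNA to 8649 of 13457 protein-coding genes, those with at least 10 reads of which at least 90% lay on 1 strand, so positions along genes cover expressed genes. Of RNA reads in all 13457 protein-coding genes, 98.55% lay on the gene's major strand. That the read strand is the transcript strand was read from H3K4me3, which held 149096 reads in the low-coordinate 500 bp of plus-strand genes against 8622 at the other end, and the reverse on minus-strand genes. The side on which H3K4me3 lies is therefore assumed and not a result. Heights along genes are ratios of summed reads, with intervals from 100 bootstrap draws of genes. Pericentromeres were set from the RNA in place of the annotation: per chromosome, the longest run of 100 kb windows whose share of steps with an RNA read, averaged over 5 windows, was under 50% of the chromosome's median. This rule was chosen after seeing the data. On chromosome 4, where the table fits throughout, the designed rule on the share of protein-coding genes was also run.

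Relations with RNA and between marks are Spearman's rho across genes, which are not independent replicates, on log2 ratios with 0.5 reads added and log2(RPKM + 0.1). For pairs of marks, H3 reads were split at random so that the marks did not share a denominator. Co-occurrence was set against the product of both gene numbers divided by all genes, and against unchanged libraries simulated from H3, which hold every gene at a ratio of 1. Gene lists, fixed before the data were examined, were compared with 10000 random lists matched on quintiles of H3 reads per kb and of gene length. A percentile describes these libraries and is not a p-value. Of the 230 list members, all were found by locus in the table, and 112 lay in the stretches. Antisense-transcribed genes had at least 10 reads and 10% of reads on the minor strand, were at least 1 kb long, and had only neighbours within 500 bp whose RNA lay mostly on the same strand. That last condition cannot see an unstranded overlapping antisense gene, so genes with no annotated neighbour were also examined. The strand of antisense-transcribed genes is that with most RNA reads, a bare majority in some, so those with at least 80% of reads on it were also examined.

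The named genes follow a rule fixed before the data were examined: per mark, the 3 protein-coding genes with the highest lower limit, the first 3 members of each list that lay in the stretches with up to 4 extreme members, the 5 highest in RNA, the 5 antisense-transcribed genes with most minor-strand reads, and the 3 genes highest for both H3K4me3 and H3K27me3. The rule counted members of the whole list, and taking the first that lay in the stretches is a departure from it. AG, CRU2, RPS6B, PRR5, CBF1 and FIE fall under the rule and were left out of the text.

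The calling rule was tested on simulated data, with 200 of 13457 genes changed by known folds and the rest unchanged. At the depth of H3K36me3, 90.0% of genes changed 2.5-fold and 100.0% of those changed 4-fold were called, with 12 calls among unchanged genes. At the depth of H3K9me2 these were 86.0% and 92.0%, with 75 calls among unchanged genes. That number exceeded a limit of 60 set for the test beforehand, and the limit was then raised to 1% of genes without changing the calling rule. For this reason calls in simulated unchanged libraries are printed beside the numbers of enriched protein-coding genes and some overlaps, but not beside those of other gene classes or windows. Alternatives tried were Input as denominator, other fold and read thresholds, the first 1 kb of genes, another scaling, thinning to the smallest library, unmoved reads, another RNA pseudocount and filter, other denominators and 1 kb windows for pairs of marks, and a stricter antisense share.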

Results

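The data comprised 12 libraries that map 9 modifications of histone H3, unmodified H3, input chromatin and transcripts in Arabidopsis. The marks were methylation of lysines 4, 9, 27 and 36 and acetylation of lysines 9 and 18. Each was measured in 1 library, so values carry counting intervals and no replicate spread. Nuclear reads numbered 926160 for H3K9me2, 1116769 for H3K27me1, 1629739 for H3K9Ac, 1822660 for H3K36me2, 2139451 for H3K4me3, 2185725 for H3K27me3, 2294023 for H3K4me2, 3579683 for H3K18Ac and 3704868 for H3K36me3. H3 held 5758273, Input 7000112 and RNA 4136951 nuclear reads.

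The first question was how the marks divide between pericentromeric heterochromatin and the gene-rich arms. Measured over H3, H3K9me2 and H3K27me1 were higher in pericentromeres, and the other 7 marks were higher in the arms. Relative to H3, H3K9me2 was 9.26 times higher in pericentromeres than in arms (95% interval 9.21 to 9.32), and H3K27me1 was 6.47 times higher (6.44 to 6.5). Of all H3K9me2 reads 84.3% fell in pericentromeres, which make up 19% of the genome, as did 78.9% of H3K27me1 reads and 36.7% of H3 reads. The opposite order held for H3K4me2, 7.97 times higher in the arms, and for H3K36me3, 7.79 times higher in the arms. H3K18Ac was the least unequal of the arm marks, at 2.37 times. With 19.6% of its reads in pericentromeres, near their 19% of the genome, it was low there only relative to H3. Input over H3 gave a ratio of 0.927 (0.925 to 0.929), which is the background of this comparison. Pericentromeres were defined by low RNA, which by itself lowers marks that follow RNA there. With the region set from protein-coding genes instead, on chromosome 4 alone and chosen after seeing the data, H3K9me2 was 8.11 times higher in the pericentromere and H3K27me1 5.42 times, and the other 7 marks stayed between 0.0862 (H3K4me2) and 0.391 (H3K18Ac).

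**Figure D1:**
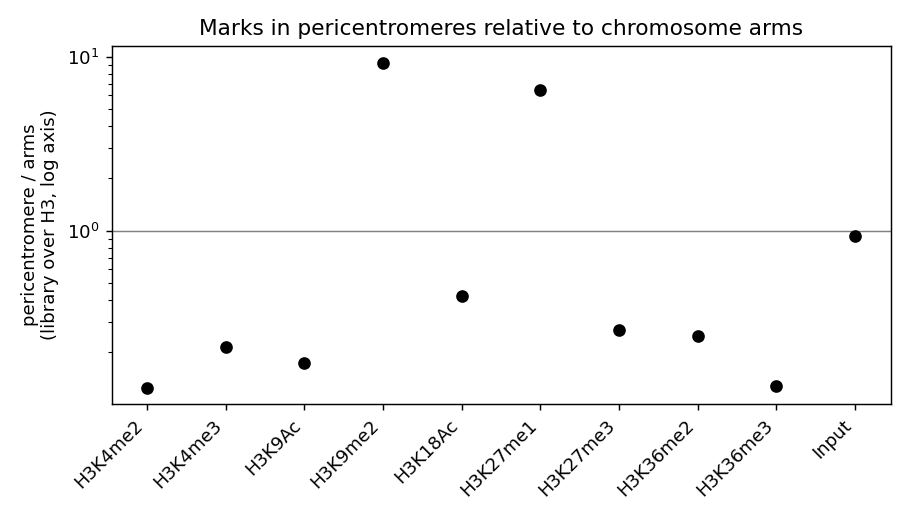
Pericentromere to arm ratio of each library over H3 (log axis), with 95% counting intervals that are mostly smaller than the points. H3K9me2 at 9.26 and H3K27me1 at 6.47 lie above 1, and the other 7 marks lie between 0.125 (H3K4me2) and 0.422 (H3K18Ac).

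The pericentromeres were the low-RNA runs from 12600001 to 16800000 on chromosome 1, 1800001 to 6700000 on chromosome 2, 10700001 to 16400000 on chromosome 3, 2700001 to 5900000 on chromosome 4 and 10000001 to 14700000 on chromosome 5. A further low-RNA run on chromosome 4, from 1600001 to 2200000, had H3K27me1 at 1.80 times H3 (1.76 to 1.83) and H3K9me2 at 1.38 times (1.35 to 1.41), while H3K4me2 stood at 0.175 (0.169 to 0.182). The short arm of chromosome 4 is known to carry a heterochromatic knob in this ecotype.

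Across the whole genome, the marks differed in how far they ran on without a break. H3K9me2 was enriched in 5673 windows of 1 kb, 85.3% of them in pericentromeres, and its longest unbroken run covered 122 kb on chromosome 5, from 11804001 to 11926000, at 3.80 times H3 (3.75 to 3.86). H3K27me1 was enriched in 6125 windows, with its longest run of 63 kb ending at the same place, from 11863001 to 11926000. The H3K9me2 run held 48866 H3 reads and the H3K27me1 run 28562, so reads shared with repeated copies cannot be excluded there. Among the other 7 marks H3K27me3 had the longest run, 35 kb on chromosome 3 from 7714001 to 7749000 at 7.73 times H3 (7.26 to 8.24), and 18.6% of its 21168 enriched windows lay in runs of at least 10 kb. By contrast, H3K4me3 was enriched in 20151 windows and had no run above 9 kb. H3K36me3 was enriched in 26443 windows, H3K4me2 in 25837, H3K36me2 in 23233, H3K9Ac in 21575 and H3K18Ac in 20824. Between the controls, Input over H3 passed the same rule in 9915 windows, more than H3K9me2 or H3K27me1. Of these, 11.1% lay in pericentromeres, and the longest run was 17 kb. H3 over Input passed in 2536 windows, 52.5% of them in pericentromeres, with a longest run of 12 kb.

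The second question was which genes carry each mark. Among 13457 protein-coding genes, H3K36me3 was enriched over 5981, H3K4me2 over 5456, H3K4me3 over 4950, H3K9Ac over 4538, H3K36me2 over 4363, H3K27me3 over 2946 and H3K18Ac over 2196. Simulated unchanged libraries gave between 21 and 41 such calls for these 7 marks. They hold every gene at a ratio of 1, whereas the arms as a whole stood at 1.27 (H3K18Ac) to 1.47 (H3K4me2) times H3. A mark spread evenly over the arms would therefore give more calls than these, and that background was not simulated. H3K9me2 was called over 31 protein-coding genes and H3K27me1 over 43, fewer than the 84 and 51 calls in simulated unchanged libraries. That simulation sets every gene at a ratio of 1, far above the median gene, so the numbers 31 and 43 show neither presence nor absence of a marked set. The median gene held 0.0531 times the H3 level for H3K9me2 and 0.126 times for H3K27me1. H3 over Input passed the same rule in 89 genes and Input over H3 in 128. The numbers depend on scaling: with libraries scaled to the median 1 kb window, H3K4me3 was called over 8449 genes, H3K36me2 over 8599, H3K27me1 over 1060 and H3K18Ac over 1025.

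Genes annotated as pseudogenes without a note of transcription, the class that holds transposon genes, differed as a class from protein-coding genes. Most of those tested were enriched for neither H3K9me2 nor H3K27me1, but a larger share was than among protein-coding genes. Genes of every class were measured only in the stretches, which leave out most pericentromeric sequence, including all of it on chromosomes 1 and 3. Pericentromeric and arm pseudogenes were not separated, so whether the difference goes with position was not tested. H3K9me2 was enriched over 294 of 1164 tested pseudogenes (25.26%) and H3K27me1 over 270 of 1168 (23.12%), whereas H3K4me3 was enriched over 13 of 1160 and H3K36me3 over 16 of 1164. Summed over the class, H3K9me2 stood at 1.95 times H3 (1.93 to 1.961), against 0.114 (0.113 to 0.116) over protein-coding genes. The 346 transcribed pseudogenes differed from these, with H3K9me2 enriched over 4 of 256 tested and H3K27me3 over 115 of 298. Of 1658 genes annotated as long noncoding RNA, H3K4me3 was enriched over 302, H3K18Ac over 267, H3K27me3 over 259 and H3K9me2 over 2. Only 492 (H3K9me2) to 985 (H3K18Ac) of them held enough reads, a minimum that counts the mark's own reads, so their shares were not compared with other classes.

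Single genes were ranked by the lower limit of their ratio. ERF4, a transcriptional repressor of the ethylene response, led both H3K4me3 at 21.9 times H3 (14 to 35.8) and H3K9Ac at 32 times (20.5 to 52.2). It was followed for H3K4me3 by PSAK, a photosystem I subunit, at 21.7 (13.7 to 35.9), and FTRA2, a subunit of ferredoxin-thioredoxin reductase, at 20.4 (13.1 to 33.5). FTRA2 was also highest for H3K36me3 at 10.9 (6.93 to 17.9), before AT3G07480 at 9.33 and AT1G19740 at 8.44. For H3K9Ac the next were AT1G13360 at 28.9 and RALFL33, a signalling peptide gene that overlaps another gene, at 30.5 (16.3 to 63.2, from 11 H3 reads). H3K4me2 was highest over EDA8 at 9.06 (6.68 to 12.5), DIC2, a mitochondrial dicarboxylate carrier, at 9.52, and AT1G19210, which overlaps another gene, at 9.01. H3K18Ac was highest over AT3G16510 at 7.60 (5.20 to 11.4), AT5G16200 at 7.42 and AT1G13360 at 6.59.

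H3K27me3 was highest over AT1G14950 at 15.7 times H3 (11.2 to 22.7), AT5G22170 at 17.3 (10.9 to 28.9) and DRNL, a regulator of organ initiation, at 14 (10.7 to 18.6). The first 2 had 0 RNA reads and DRNL had 1. H3K36me2 was highest over AT4G16955 at 6.35 (4.95 to 8.19) and AT4G31354 at 5.63, both overlapping other genes, and over GUN5, a subunit of magnesium chelatase in chlorophyll synthesis, at 4.92 (4.27 to 5.68). H3K9me2 was highest over AT2G01023 at 5.62 (4.85 to 6.5), AT2G01008 at 3.99 and AT5G10340 at 3.85, and H3K27me1 over AT5G03710 at 6.17 (4.89 to 7.80), AT2G01008 at 4.93 and AT2G01021 at 5.10. AT5G03710 and AT2G01008 overlap other genes. AT2G01008 alone held 4063 H3 reads, so reads shared with repeated copies cannot be excluded for this gene and its neighbours AT2G01021 and AT2G01023. The files hold 1 read per position and strand, and AT2G01008 held 4076 H3K18Ac and 3882 H3K27me1 reads despite smaller libraries. AT2G01021 held 191 H3, 191 H3K18Ac and 189 H3K27me1 reads. H3 and H3K18Ac held 438 and 436 over AT5G10340, and 392 and 377 over AT2G01023. Such near-equal counts point to that limit, so ratios, intervals and ranks of these genes partly follow library size.

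The third question was where along genes the marks lie, in 6037 expressed genes of at least 2 kb. H3K4me3 reached 7.95 times H3 (7.81 to 8.11) in the step from 300 to 400 bp after the gene start. H3K36me3 peaked in the same step at 5.34 (5.24 to 5.44), H3K9Ac from 200 bp at 5.11 (5.01 to 5.24), H3K4me2 from 400 bp at 3.92 (3.87 to 3.98) and H3K18Ac from 200 bp at 2.08 (2.05 to 2.12). H3K36me2 stood apart, with its maximum of 3.35 (3.30 to 3.42) between 900 and 800 bp before the gene end, 3.27 over the stretch from 1000 to 500 bp before the end, and only 0.719 in the first 500 bp. Over those first 500 bp H3K4me3 stood at 7.17 and H3K36me3 at 4.92, and in the last 500 bp they stood at 0.412 and 0.512. H3K9me2 did not exceed 0.177 times H3 and H3K27me1 did not exceed 0.260, and H3K27me3 reached 1.25. Input over H3 itself reached 1.84 (1.81 to 1.88) just upstream of the start, so ratios there depend on the control.

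**Figure D2:**
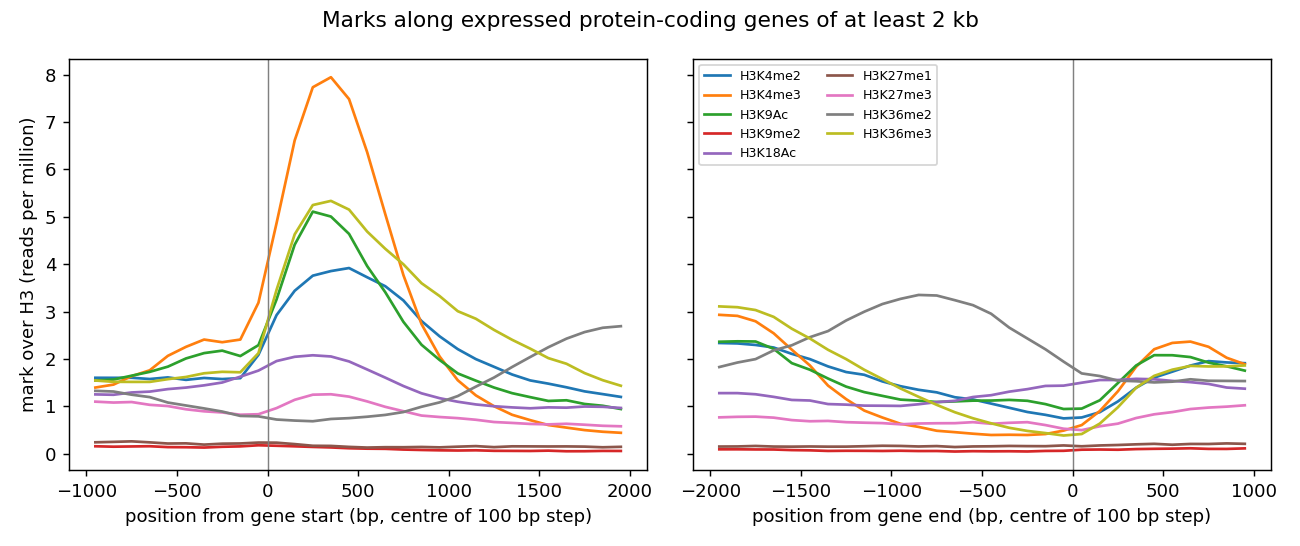
Mark over H3 in 100 bp steps around the start and the end of 6037 expressed protein-coding genes of at least 2 kb, 1 line per mark. H3K4me3 reaches 7.95 and H3K36me3 5.34 shortly after the start, and H3K36me2 reaches 3.35 before the end.

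The fourth question was how the marks relate to transcript level. Across 13457 genes, H3K36me3 (rho 0.772) and H3K4me3 (0.766) followed RNA most closely, followed by H3K9Ac (0.678), H3K36me2 (0.558) and H3K4me2 (0.460). H3K27me3 went the other way (-0.331), as did H3K27me1 (-0.225). The H3K27me1 value rests on few reads per gene, the median gene being at 0.126 times H3. From the lowest to the highest quintile of RNA its medians, with 0.5 reads added, were 0.188, 0.232, 0.159, 0.132 and 0.131, without a steady fall. The 0.126 was taken without added reads, in genes with at least 20 reads, so it does not compare with these medians. H3K36me3 was enriched over 82.7% of genes in the highest quintile of RNA and 0.9% in the lowest, and H3K4me3 over 76.4% and 1.0%. H3K27me3 was enriched over 57.2% of genes in the lowest quintile and 5.1% in the highest, and 53.8% of the genes it marked had 0 RNA reads. H3K36me2 was already at 48.8% in the middle quintile and 45.4% in the highest. H3K18Ac hardly followed RNA (rho -0.031), with 20.4% of genes enriched in the lowest quintile and 17.2% in the highest.

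Part of these relations separates genes with few or no RNA reads from the others. Among the 10644 genes with any RNA read, rho was 0.636 for H3K4me3, 0.644 for H3K36me3, -0.093 for H3K27me3 and -0.248 for H3K27me1. Among genes with at least 10 RNA reads, it was 0.530 for H3K4me3, 0.521 for H3K36me3, 0.112 for H3K4me2, 0.056 for H3K36me2, 0.079 for H3K27me3 and -0.219 for H3K27me1. Over the first 1 kb of genes with a known strand it was 0.009 for H3K4me2, 0.121 for H3K27me3 and -0.146 for H3K36me2. The RNA came from older plants grown in another way than those used for chromatin.

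**Figure D3:**
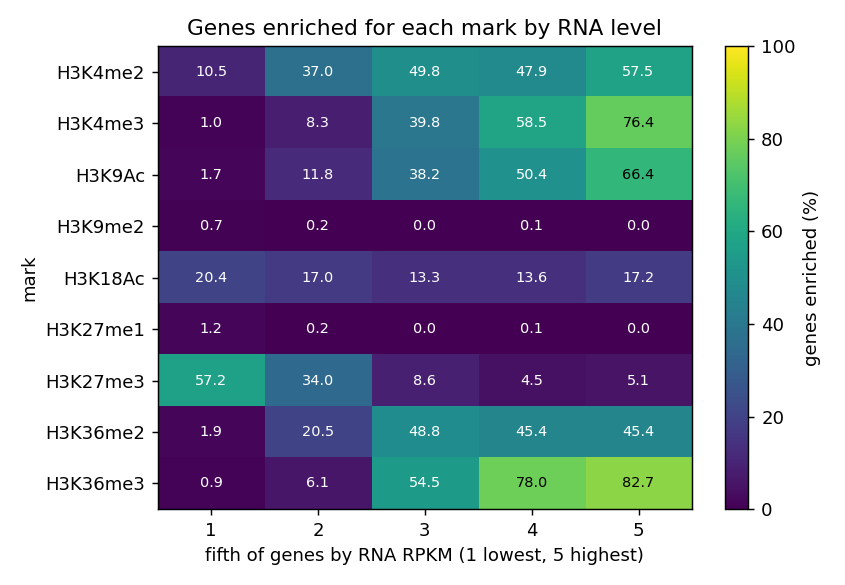
Percent of genes enriched for each mark in each quintile of 13457 protein-coding genes by RNA level. H3K36me3 goes from 0.9% in the lowest to 82.7% in the highest quintile, and H3K27me3 from 57.2% to 5.1%.

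The 5 genes highest in RNA included ATPC1, the gamma subunit of the chloroplast ATP synthase, with 190.3 RPKM, and LHCB6, a light-harvesting protein of photosystem II, with 167.7 RPKM. ATPC1 carried H3K4me3 at 14.6 times H3 and H3K36me3 at 7.85 times. EMB3136 had 161.7 RPKM with H3K4me3 at 9.10, and AT4G16983 had 161.4 RPKM with H3K9Ac at 12.5. AT4G38775, the highest at 191.4 RPKM, differed from these with H3K27me3 at 8.04 and H3K36me3 at 0.614. LHCB6, EMB3136, AT4G16983 and AT4G38775 overlap other annotated genes, and RNA reads of those genes on the same strand are counted too.

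Gene groups fixed beforehand divided along the same lines. Regulators of flowers and meristems were covered by H3K27me3 in 12 of 13 members measured, with a median of 7.04 times H3. The floral repressor FLC stood at 10.2 (8.59 to 12.2), the floral organ gene SEP3 at 10.5 (8.22 to 13.6) and the petal and stamen gene PI at 8.17 (6.32 to 10.6). CUC1, a boundary gene, was the exception at 1.02 (0.674 to 1.51). Over the whole gene none of the 13 was enriched for H3K4me3, H3K9Ac, H3K36me2 or H3K36me3. In the first 1 kb, which could be placed for only 2 of the 13, the log2 median was 1.37 for H3K4me3. Seed and embryo genes were enriched for H3K27me3 in 10 of 10, with a median of 8.45, among them the storage protein genes CRU3 at 11.2 (9.45 to 13.3) and SESA4 at 10.6 (7.91 to 14.4), the embryo regulator LEC2 at 7.95 and its partner LEC1 at 4.94, and 8 of the 10 had 0 RNA reads. Root markers were enriched in 7 of 7, with a median of 7.95, including the stem cell gene PLT1 at 8.44 (7.06 to 10.14), the quiescent centre gene WOX5 at 8.23 (5.75 to 12), the radial patterning gene SHR at 7.96 (6.69 to 9.51) and the iron transporter IRT1 at 7.20. The H3K27me3 medians lay at percentiles 100, 100 and 99.98 of matched random lists.

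Photosynthesis genes carried most of the marks that go with RNA. All 25 measured members were enriched for H3K4me3 and H3K4me2, 24 for H3K9Ac, 21 for H3K36me3 and 18 for H3K36me2, and none for H3K27me3. H3K18Ac was enriched over 2 of them, with its median at percentile 0.98. Their median H3K4me3 was 9.80 times H3 and their median RNA 124.6 RPKM, both at percentile 100. PSAK was highest at 21.7, and the light-harvesting genes LHCB1.2 at 5.03 (3.97 to 6.42), LHCB1.1 at 6.33 (4.91 to 8.22) and LHCB1.3 at 9.22 (7.16 to 12) included the lowest. These last 3 are near-identical copies, and how reads were shared between them is not known.

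Housekeeping genes were enriched for H3K4me3 in 11 of 12, with a median of 4.41, from UBQ11 at 12.4 (9.70 to 16.1) and UBQ10, both polyubiquitin genes, at 11.2 (9.32 to 13.6) to ACT2 at 3.31 (2.58 to 4.25), with the phosphatase subunit PP2AA3 at 0.968 (0.716 to 1.3). Ribosomal protein genes were enriched for H3K4me3, H3K9Ac and H3K36me3 in 8 of 8, RPL4A reaching 7.79 (6.25 to 9.79) for H3K36me3 and RPS6A 2.11 (1.58 to 2.83). Clock genes were enriched for H3K36me3 in 5 of 6, CHE at 5.63 (4.39 to 7.31) and RVE8 at 4.32 being highest, with PRR7 at 1.80 (1.48 to 2.18), LHY at 2.16 and GI at 2.13. Their median lay at percentile 64.76, within the middle of matched lists. Chromatin regulators were enriched for H3K36me3 in 10 of 12, for example HDA19, a histone deacetylase, at 3.97 (3.36 to 4.71) and ATXR5, an H3K27 methyltransferase, at 3.54 (2.76 to 4.56), with SWN, a Polycomb methyltransferase, at 2.75 (2.33 to 3.27), and KYP, an H3K9 methyltransferase, at 1.91 (1.58 to 2.30). Their median H3K36me3 lay at percentile 93.9 and their median H3K27me3 of 0.347 at percentile 0.37.

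Stress and defence genes and leaf cell type markers were mixed. The cold regulators CBF2 and CBF3 carried H3K4me2 at 6.39 and 5.34 times H3, and H3K27me3 at only 0.419 (0.159 to 0.938) and 0.623 (0.312 to 1.16). The flavonoid enzyme gene CHS had H3K27me3 at 4.61 (3.48 to 6.15) and RD22 at 5.93 (4.69 to 7.54), with 121.5 and 82.4 RPKM of RNA, and KIN1 at 2.63. H3K4me2 was enriched over 5 of the 6 measured stress genes, with a median of 3.83 at percentile 99.74 of matched lists. Among cell type markers, the stomatal regulators MUTE at 7.57 (5.65 to 10.3) and FAMA at 6.67 (5.47 to 8.17) carried H3K27me3, as did the phloem sucrose carrier SUC2 at 2.43 (1.84 to 3.19), whereas TTG1 at 1.04 and MYB60 at 0.995 did not pass. EPF2 did not pass either. The median H3K27me3 of the 6 markers was 3.26, at percentile 99.54 of matched lists. Of 2 pollen and sperm markers measured, HTR10, a sperm histone gene, had H3K27me3 at 6.79 (4.89 to 9.54) and ACA9 at 0.485 (0.348 to 0.661). Among silenced loci, the transposon gene GP1 carried H3K9me2 at 3.81 (3.48 to 4.16) and H3K27me1 at 3.27 (2.99 to 3.57). MU1 had H3K9me2 at 1.29 (0.924 to 1.78), EVD at 0.661 and COPIA4 at 0.268. COPIA4 was not silent here, with 1023 RNA reads (56.2 RPKM), whereas MU1 and EVD had 0. The imprinted gene FWA had H3K9me2 at 0.0401 (0.00101 to 0.227) and H3K27me3 at 3.20 (2.57 to 3.98).

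**Figure D4:**
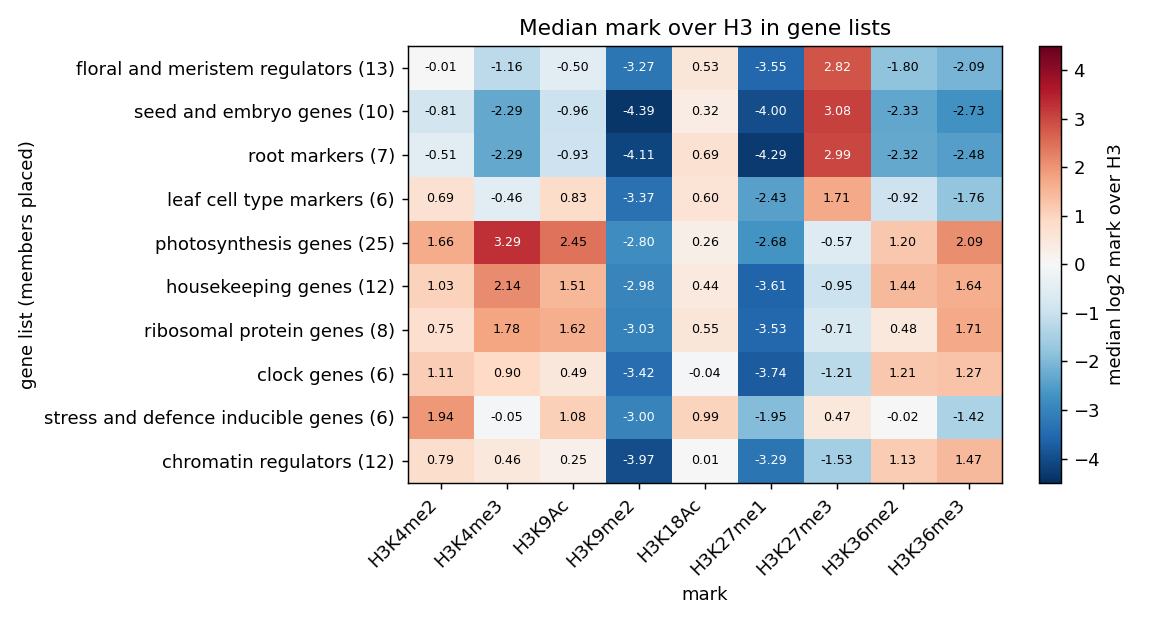
Median log2 mark over H3 in the gene lists with at least 5 protein-coding members measured, with the number of members beside each list. H3K27me3 is highest in floral, seed and root genes (2.82, 3.08 and 2.99), and H3K4me3 in photosynthesis genes (3.29).

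The fifth question was which marks share genes. H3K4me3 and H3K9Ac were the closest pair across genes (rho 0.855), then H3K4me3 and H3K36me3 (0.842), while H3K27me3 and H3K36me2 were the most opposed (-0.582). Across 1 kb windows of the whole genome, pericentromeres included, the last pair stood at only -0.147, and H3K4me2 and H3K9me2 were the most opposed (-0.467). The closest pair across windows was H3K4me2 and H3K36me3 (0.749), with H3K4me3 and H3K9Ac at 0.694. Simulated unchanged libraries gave rho of 0.007 and -0.009 for H3K4me3 with H3K9Ac and for H3K27me3 with H3K36me2. With the same H3 reads under both marks, the covariance of H3K4me3 and H3K9Ac was 1.93 against 0.041 in simulation, and that of H3K27me3 and H3K36me2 was -1.31 against 0.037. The most frequent state was none of the 9 marks, in 1759 genes, followed by H3K27me3 alone in 1594 and by H3K4me2, H3K4me3, H3K9Ac and H3K36me3 together in 1116.

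Only 165 genes were enriched for both H3K4me3 and H3K27me3, against 1083.7 for independent lists and 1 in simulated unchanged libraries. The highest were AT2G02455 with 7.08 (4.1 to 12.7) and 8.74 (5.16 to 15.5), PTF1, a transcription factor gene, with 4.99 (3.56 to 7.06) and 6.42 (4.66 to 8.95), and AT4G33040 with 8.18 (5.15 to 13.4) and 4.53 (2.71 to 7.74). Across 1 kb windows of the whole genome, the relation of these 2 marks had the other sign, rho 0.194 against -0.267 across genes. The windows include pericentromeres, where H3K4me3 stood at 0.216 and H3K27me3 at 0.269 of their arm levels. Low levels of both there raise rho across windows by themselves, so the 2 values do not compare like sets. H3K9me2 and H3K27me1 shared 16 protein-coding genes against 0.1 for independent lists and 6 in simulation. AT2G01008, AT2G01021, AT2G01023 and AT5G10340, where 1 read per position and strand limits the counts, were called for both marks over the same H3 reads. The overlap of the 31 and 43 calls is therefore no evidence that the 2 marks share genes. The rho of H3K9me2 and H3K27me1 was 0.153 across genes and 0.501 across windows. H3K27me3 shared 33 genes with H3K36me3 where independent lists would give 1309.4, but 845 with H3K18Ac where they would give 480.7.

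The last question concerned antisense transcripts. Of 3463 genes that could be examined, 91 (2.63%) had antisense reads above the threshold, and the last 500 bp of these genes differed from other gene ends in several marks. The gene end was placed by the strand with most RNA reads, which in these genes is not a 90% majority. H3K4me3 there had a median of 1.92 times H3, against 0.512 in matched genes (95% of matched lists between 0.419 and 0.608). H3K4me2 stood at 2.42 against 1.05, H3K9Ac at 2.57 against 1.18, and H3K36me3 at 1.06 against 0.482, all above every one of 1000 matched lists. H3K36me2 was lower, 1.3 against 1.79 (1.5 to 2.09), and H3K27me3 was at 0.527 in both.

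The genes with most antisense reads were ATSAC1, a phosphoinositide phosphatase, with 416 of its 1113 RNA reads on the minor strand, AT1G06000 with 178 of 593, UGT75B1, a glucosyltransferase, with 164 of 374, HYR1 with 146 of 556, and AT5G19150 with 146 of 856. All 5 overlap another annotated gene, whose strand the table does not give. The 32 antisense-transcribed genes with no annotated gene overlapping or within 500 bp, a condition added after seeing the data, had H3K4me3 at 2.12 against 0.554 in matched genes (0.385 to 0.837). Their H3K36me2 lay inside the range of matched lists, 1.16 against 1.61 (1.094 to 2.1).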

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

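The comparisons in this section were chosen after the result was seen.

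Mitochondrial reads made up 1.2049% of the H3K9me2 library (95% Wilson interval 1.183 to 1.2271) and 0.8783% of the H3K27me1 library (0.8613 to 0.8957). These lie above the 0.695% of H3 and 0.7015% of Input, although no comparison of marks uses organelle reads. If organelle DNA had been carried over into the immunoprecipitates, the chloroplast and mitochondrial shares over H3 should go together over the 9 marks, but Spearman's rho was -0.55 (exact two-sided permutation p = 0.1328), which is too uncertain to decide. If the reads came from copies of mitochondrial sequence in pericentromeric chromatin, the mitochondrial share should follow the pericentromere to arm ratio among the other 7 marks, and rho was 0.857 (exact two-sided permutation p = 0.02381, adjusted 0.07143 over 6 p-values). Pearson's r for the same relation was 0.893 (exact permutation p = 0.006349, adjusted 0.03809). Among these 7 marks, rho between chloroplast and mitochondrial shares was -0.179 (exact permutation p = 0.7131). The mitochondrial share, at 0.1216 to 0.2838, and the pericentromere to arm ratio, at 0.1254 to 0.4215, lie below those of H3 in all 7 marks. Unspecific DNA in the immunoprecipitates would therefore also raise the share and the ratio together, so the relation of share and ratio has more than 1 reading. This relation therefore decides nothing. Carried-over DNA made up like Input could not lift the mitochondrial share above that of Input, where H3K9me2 and H3K27me1 lie. It would also bring more chloroplast than mitochondrial reads, but their chloroplast shares were 0.1641% and 0.0905%, against 3.13% in Input. The files hold 1 read per position and strand, so all these are shares of kept positions, and the reads lost from Input in this way were not measured. Judged by kept positions, the values argue against carry-over of such DNA as the source of the excess in these 2 libraries. Carry-over of DNA of another make-up and nuclear copies cannot be told apart.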

How the results depend on the processing

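Among the alternatives below, the restrictions of antisense-transcribed genes to those without annotated neighbours and to those with a clear major strand, and the pericentromere set from genes on chromosome 4, were chosen after seeing the data. Of the values that answer a comparison, 96 stayed within their limits under an alternative, 48 moved, 20 became weaker, 14 became stronger and 8 changed sign. Of the other values, 158 stayed, 52 moved and 15 changed sign. Every pericentromere to arm ratio kept its side of 1 under the 3 alternatives run. A count within its limits need not hold the same genes: of the 2196 genes enriched for H3K18Ac, 1438 were among the 2351 with Input, 1085 among the 1953 after thinning and 1108 among the 2902 over the first 1 kb. No paired analysis was possible because each group held 1 library. Limiting reads to 1 per position and strand was not run, since the files already hold no more. Scaling to the median window gave no value for H3K9me2, whose median window holds no reads. The first 1 kb can be taken only for the 8649 genes with a known strand, among which rho with RNA over the whole gene was already 0.080 for H3K27me3, 0.069 for H3K9me2 and 0.069 for H3K18Ac, so those changes of sign come from the genes tested. For H3K36me2 it was 0.055, so its change of sign comes with the window. Changed fold and read thresholds move counts by construction. For the remaining changes the cause was not tested. On simulated data at the depth of each mark, 80% (H3K27me1 and H3K27me3) to 96.0% (H3K18Ac) of genes changed 2.5-fold were called.

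With Input as denominator, pericentromere to arm ratios were 0.135 for H3K4me2, 0.233 for H3K4me3, 0.189 for H3K9Ac, 9.99 for H3K9me2, 0.455 for H3K18Ac, 6.98 for H3K27me1, 0.29 for H3K27me3, 0.269 for H3K36me2 and 0.139 for H3K36me3. Enriched genes numbered 63 for H3K9me2 and 85 for H3K27me1. Genes with both marks numbered 29 for H3K9me2 and H3K27me1 and 6 for H3K9me2 and H3K36me2. The rank correlation with RNA was -0.108 for H3K18Ac and -0.36 for H3K27me3. Log2 list medians were -0.043 for pollen and sperm markers, H3K18Ac (reversed), 0.033 for clock genes, H3K18Ac (reversed) and 0.001 for silenced loci and transposon genes, H3K4me2 (reversed).

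With pericentromeres set by the stricter RNA limit, pericentromere to arm ratios were 0.0996 for H3K4me2, 0.2003 for H3K4me3, 0.154 for H3K9Ac, 8.38 for H3K9me2, 0.392 for H3K18Ac, 6.04 for H3K27me1, 0.224 for H3K27me3, 0.241 for H3K36me2 and 0.106 for H3K36me3.

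With the pericentromere set from protein-coding genes on chromosome 4 alone, which changes 2 choices together, pericentromere to arm ratios were 0.0862 for H3K4me2, 0.2146 for H3K4me3, 0.141 for H3K9Ac, 8.11 for H3K9me2, 0.391 for H3K18Ac, 5.42 for H3K27me1, 0.202 for H3K27me3, 0.256 for H3K36me2 and 0.102 for H3K36me3.

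With a fold threshold 1.5, enriched genes numbered 8472 for H3K4me2, 47 for H3K9me2, 5079 for H3K18Ac and 75 for H3K27me1. Genes with H3 over Input numbered 585. Genes with both marks numbered 293 for H3K4me3 and H3K27me3 and 6 for H3K9me2 and H3K36me2.

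With a fold threshold 3, enriched genes numbered 1952 for H3K4me2, 2930 for H3K4me3, 2448 for H3K9Ac, 10 for H3K9me2, 331 for H3K18Ac, 15 for H3K27me1, 836 for H3K36me2 and 3129 for H3K36me3. Genes with H3 over Input numbered 8. Genes with both marks numbered 39 for H3K4me3 and H3K27me3 and 6 for H3K9me2 and H3K27me1.

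Scaled to the median 1 kb window, enriched genes numbered 8449 for H3K4me3, 1025 for H3K18Ac, 1060 for H3K27me1 and 8599 for H3K36me2.

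Over the first 1 kb of genes with a known strand, enriched genes numbered 10 for H3K9me2, 14 for H3K27me1, 814 for H3K27me3 and 1010 for H3K36me2. These were counted as weaker against all genes, but over the whole of the same 8649 genes the numbers were 7, 7, 740 and 3885, so only H3K36me2 was lower there. H3K4me2 went from 4343 to 7554 on these genes. The rank correlation with RNA was 0.009 for H3K4me2, 0.539 for H3K4me3, 0.451 for H3K9Ac, 0.063 for H3K9me2 (reversed), 0.091 for H3K18Ac (reversed), -0.114 for H3K27me1, 0.121 for H3K27me3 (reversed), -0.146 for H3K36me2 (reversed) and 0.458 for H3K36me3. List medians rest on the members with a known strand, 2 of 13 floral, 2 of 7 root, 4 of 6 leaf cell type and 5 of 6 stress genes, and all members of the other lists named. On the log2 scale they were 1.957 for floral and meristem regulators, H3K4me2 (reversed), 1.37 for floral and meristem regulators, H3K4me3 (reversed), 0.30 for floral and meristem regulators, H3K9Ac (reversed), 0.18 for root markers, H3K4me2 (reversed), 0.38 for leaf cell type markers, H3K4me3 (reversed), -0.49 for housekeeping genes, H3K36me2 (reversed), -0.77 for ribosomal protein genes, H3K36me2 (reversed), 0.088 for clock genes, H3K18Ac (reversed), -0.74 for clock genes, H3K36me2 (reversed), 0.15 for stress and defence inducible genes, H3K36me2 (reversed) and -1.40 for chromatin regulators, H3K36me2 (reversed).

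With a minimum of 100 reads, genes with H3 over Input numbered 48.

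Among genes with at least 10 RNA reads, rho with RNA was 0.112 for H3K4me2, 0.53 for H3K4me3, 0.412 for H3K9Ac, 0.062 for H3K9me2 (reversed), 0.059 for H3K18Ac (reversed), 0.079 for H3K27me3 (reversed), 0.056 for H3K36me2 and 0.521 for H3K36me3.

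With the same H3 reads for both marks, rho between marks was 0.883 for H3K4me3 and H3K9Ac, -0.247 for H3K4me3 and H3K27me3 and 0.7 for H3K4me2 and H3K4me3.

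With split Input reads, rho between marks was 0.843 for H3K4me3 and H3K9Ac, -0.317 for H3K4me3 and H3K27me3 and 0.601 for H3K4me2 and H3K4me3.

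Across 1 kb windows of the whole genome, pericentromeres included, rho between marks was 0.694 for H3K4me3 and H3K9Ac and -0.147 for H3K27me3 and H3K36me2. It was 0.194 for H3K4me3 and H3K27me3 (reversed) and 0.501 for H3K9me2 and H3K27me1.

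With antisense reads of at least 20%, antisense-transcribed genes numbered 54. The log2 difference in the last 500 bp was -0.037 for H3K18Ac (reversed).

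Without annotated genes overlapping or within 500 bp, antisense-transcribed genes numbered 32.

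With at least 80% of reads on the major strand, antisense-transcribed genes numbered 37.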

Other observations

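The comparison of H3K18Ac between silent genes, and the comparison of antisense-transcribed genes without annotated neighbours, were chosen after seeing the data, as was the comparison of those with a clear major strand.

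H3K18Ac, an acetylation, was more frequent on genes carrying the repressive mark H3K27me3. Among genes with 0 RNA reads, H3K18Ac was enriched over 29.3% of the 1586 with H3K27me3 and 10.4% of the 1227 without it. Among genes with RNA reads the shares were 27.9% of 1360 and 13.2% of 9284. Median H3K18Ac was 1.661 against 1.193 times H3 among silent genes and 1.637 against 1.3 among genes with RNA. Median H3K9Ac was 0.5496 against 0.5353 among silent genes, and with RNA it went the other way, 0.91 against 1.87.

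Chloroplast reads made up 3.13% of Input and 0.0533% of H3, a share 58.7 times higher, whereas the mitochondrial share of Input was 1.01 times that of H3. The files hold 1 read per position and strand, and chloroplast reads numbered 227874 in Input against 3093 in H3. These are therefore shares of kept positions and not of sequenced DNA, and how far the limit lowers the Input share was not measured.

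The 165 genes enriched for both H3K4me3 and H3K27me3 could arise from marks on different parts of a gene or from reads of a neighbouring gene. Against the first, 89.1% of them (83.3 to 93.4) held a 500 bp step in which both marks passed. Against the second as the whole source, such genes were 2.964 times as frequent (2.189 to 4.012) among genes with no annotated gene overlapping or within 500 bp as among the others. They numbered 79 of 3184 genes without such a neighbour and 86 of 10273 with one. Neighbour reads are not excluded for those 86, and the frequency of each single mark in the 2 sets was not compared. Cells of different kinds that each carry 1 of the marks would give the same reads in mixed aerial tissue, and the design cannot test this.

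H3K4me3 at the 3' end of antisense-transcribed genes could come from the start of a neighbouring or overlapping gene, or from the gene's own start if the strand with most RNA reads is not its own. Among the 32 such genes with no annotated gene overlapping or within 500 bp, the log2 difference from matched genes was 1.932, close to the 1.91 of all 91 genes, which argues against annotated neighbours as the whole source. Among the 37 with at least 80% of reads on the major strand it was 1.899, which argues against a wrong strand there, while the strand of the other 54 is less sure. Genes meeting both conditions were not examined as a set, so a mixture of both sources is not excluded. A start of antisense transcription inside these genes remains a hypothesis, and no biological explanation was tested, since RNA and chromatin came from different plants.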
